A study of Rattus norvegicus with 12 samples.

How the data were processed

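Gene expression was measured in the inferior colliculus (IC), the auditory midbrain centre, of Sprague-Dawley rats. Per the labels, 20 rats had the right cochlea ablated and 20 had a sham operation, and tissue was taken after 2 weeks. The 12 arrays form 4 groups of 3: left and right IC of control rats, and left and right IC of single-sided deaf rats. The labels conflict in part. The series title and the sample descriptions name hippocampus, whereas the sample titles, source names, tissue entries and design text name IC, which was taken as the tissue. The labels do not say whether an array holds 1 rat or a pool, nor whether left and right arrays of the same number share rats. The p-values therefore measure the spread between these arrays, which may be partly technical.

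Per the labels, total RNA was converted to single-stranded cDNA, fragmented, labelled with biotin and hybridised to 1-colour Affymetrix arrays. The array model and the summarisation and normalization software are not given in the sources used here. The deposited values are log2 intensities made comparable between arrays by the authors. They ran from 1.33 to 13.1, the median was 5.34 on each array, and at any rank the 12 arrays differed by at most 0.0995. Correlations between arrays were 0.984 to 0.994. The number of arrays limits the precision.

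Of 29489 probes, 18511 were listed with 1 gene symbol, 575 with several and 10403 with none. Probes with 1 symbol were used, and for the 291 genes with more than 1 probe the brightest was kept, which left 18166 genes. No filter on dim genes was applied. Detection calls are not given in the sources used here, so differences of dim genes are given as measured, not as bounds. Symbols were compared with the reference through 18394 matched Entrez identifiers, and 0 symbols changed. No genomic positions are given, because the array's genome build is not given in the sources used here.

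Linear models were fitted with limma 3.58.1 in R 4.3.3, with 4 group means and 6 contrasts: deaf minus control on the left, on the right and as the mean of both sides, left minus right in control and in deaf rats, and the side by deafness interaction. All 12 arrays shared an estimate of the spread (8 residual degrees of freedom, 3.79 prior degrees of freedom, median residual SD 0.152). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, so limma adjusted p-values are reported.

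The contrasts, the gene lists and the rule for named genes were chosen before the data were examined. The 28 gene lists covered responses to deafferentation, cell types, and neighbouring tissue that a dissection could hold; 669 of their 780 listed members were measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry, by its directional test and by its mixed test for changes in either direction. Members were also adjusted over the list alone. A list score is the mean of the members' gene-centred log2 values on an array. Named genes were those past the threshold with non-overlapping arrays. Where too few passed, the genes of smallest unadjusted p with non-overlapping arrays and a log2 change of at least 0.3 were given as values that did not pass, up to 6 per direction for deaf against control on each side and up to 3 otherwise. Unnamed, predicted, microRNA, olfactory and vomeronasal receptor genes were skipped (for deaf against control, 4 higher and 2 lower on the left, and 4 higher and 3 lower on the right). Up to 4 members per list with the smallest p were added.

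The fit was tested on simulated data with 18166 genes. Of 100 genes changed 1.5-fold it called 58, and of 100 changed 2-fold it called 84, with 11 false calls. Both sets were changed in the same simulated arrays. With fewer changed genes the adjusted threshold is harder to pass, so these counts may be too high for data with few changes. A list of 20 genes shifted by 0.2 was called in 20 of 20 simulations. Over the same 20 simulations, 2 list calls were false on the unchanged side. The simulated noise was independent between genes, so these counts do not show how camera does on correlated members. The shift of 0.2 also exceeded the mean change of that list, the glucocorticoid list, in the data (0.078 left, 0.13 right).

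The alternatives were quantile normalization, centring each array on its median, genes above the median level, all probes, the mean of a gene's probes, a variance trend with robust estimation, array weights, only the groups compared, blocks by replicate number, other thresholds and leaving out each array in turn. An exact permutation test of list scores, the omission of right controls 1 and 3 together, a meningeal covariate and the omission of arrays for members adjusted over the list alone, for the mixed test of fry and for the mean change of called lists, and the search for lists called under only some settings, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.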

Results

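Expression of 18166 genes was measured in the IC 2 weeks after ablation of the right cochlea or a sham operation, with 3 arrays in each of 4 groups. The left IC receives most of its input from the ablated right ear, and the right IC most of its input from the intact left ear. Values are log2 intensities, and changes are differences of group means with their standard error (SE) and n = 3 arrays per group. The first principal component held 21.1% of the variance, and right control 3 lay farthest out on it, at 27.3.

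In the left IC, opposite the ablated ear, Vgf was the gene with the smallest p-value. Vgf (Entrez 29461), which encodes a neurotrophin-inducible secretory peptide precursor, had a mean of 8.17 ± 0.17 (SD, n = 3) in control and 7.29 ± 0.21 in deaf rats, a log2 difference of -0.88 (SE 0.11), and all 3 deaf arrays lay below all 3 controls. Within the list for axon growth and neurotrophin signalling, 2 of 29 measured members fell when adjusted over the list alone: Vgf (limma adjusted p = 1.8e-04) and Sprr1a, a gene induced in injured neurons (-0.56, SE 0.13, adjusted p = 0.0152). Over all genes neither passed (limma adjusted p = 0.110 for Vgf and 0.986 for Sprr1a). The adjustment over the list alone takes no account of the other lists tested. The list as a whole was not called (camera adjusted p = 0.516). With each of the 12 arrays left out in turn, Vgf stayed past the threshold over the list alone (adjusted p up to 0.00157), whereas Sprr1a was lost in 4 of the 12 fits (up to 0.0909, without left control 1).

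Markers of the meninges and fibroblasts were higher in the left deaf IC: 19 of 20 measured members had higher means, by 0.27 on average (camera adjusted p = 0.00638; adjusted p = 0.775 with an estimated correlation). None of the 20 passed adjusted over the list alone, and the examples Slc13a4 (0.61, SE 0.37), Ogn (0.55, SE 0.37) and Fmod (0.43, SE 0.30) had overlapping arrays and were at 0.26, 0.24 and 0.20 without left deaf 2. The meningeal score was 0.58 on left deaf 2 and at -0.064 and -0.15 on the other left deaf arrays. Without left deaf 2 the mean change was 0.035 (camera adjusted p = 0.715), and without left control 3 it was 0.16 (0.279); without left deaf 3 it was 0.40. Glucocorticoid-responsive genes were higher by 0.078 on average, in 12 of 20 members (camera adjusted p = 0.0395; adjusted p = 0.775 with an estimated correlation). Of these members, Sgk1, a kinase gene induced by glucocorticoids, rose by 0.31 (SE 0.074; limma adjusted p = 0.0260 over the list alone). The list was no longer called without left control 2 (0.345, mean change 0.050), left deaf 1 (0.118), left deaf 3 (0.0761), right deaf 2 (0.0707), right control 3 (0.0593), right deaf 1 (0.0523), right control 2 (0.0520) or right control 1 (0.0503). With the meningeal score as a covariate, added after the data were seen, it was not called either (0.0883); its mean change was then 0.070 (SE 0.045 over the arrays), against 0.078 (SE 0.041). Sgk1 on the left was lost over the list alone in 5 of 12 such fits (up to 0.122, without left deaf 2).

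Other named genes of the left contrast are values that did not pass over all genes. Those with higher values were Tnp1 (0.41, SE 0.079), Ccn2 (0.39, SE 0.087), Rpa3l1 (0.78, SE 0.18), Vsx1 (0.51, SE 0.12) and Tnni2 (0.69, SE 0.17). Those with lower values were Prtn3 (-0.58, SE 0.10), Rup2 (-0.76, SE 0.13), Elovl2 (-0.35, SE 0.074), Itga7 (-0.40, SE 0.085) and Kcnk15 (-0.52, SE 0.11). Among transmitter genes, the neuropeptide gene Penk had a change of -0.34 (SE 0.092, adjusted p = 0.0785 over the list alone), Nts -0.46 (SE 0.21), Gad1, a GABA-synthesis gene, -0.23 (SE 0.12), and the channel gene Hcn2 -0.26 (SE 0.091). The interferon-response gene Ifit3 was 0.47 higher (SE 0.17). With limma 0 of 18166 genes passed the adjusted threshold, against 670 at an unadjusted p under 0.05 (309 higher, 361 lower). Arrays of the groups did not overlap for 1874 genes (10.3%), where chance gives 10%. Of the 28 lists 2 were called, and none with an estimated correlation or with the directional test of fry. The mixed test of fry, which takes changes in either direction, called the list for axon growth and neurotrophin signalling (adjusted p = 0.00377). With 1 array left out camera called 1 to 2 lists, among them the endothelial list without left deaf 2 (lower, 0.0132) and the neuropeptide list without left deaf 3 (lower, 0.0324). The call of the mixed test was lost without left control 1 (0.0559), left control 2 (0.236), left deaf 1 (0.0761) or left deaf 2 (0.235).

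**Figure D1:**
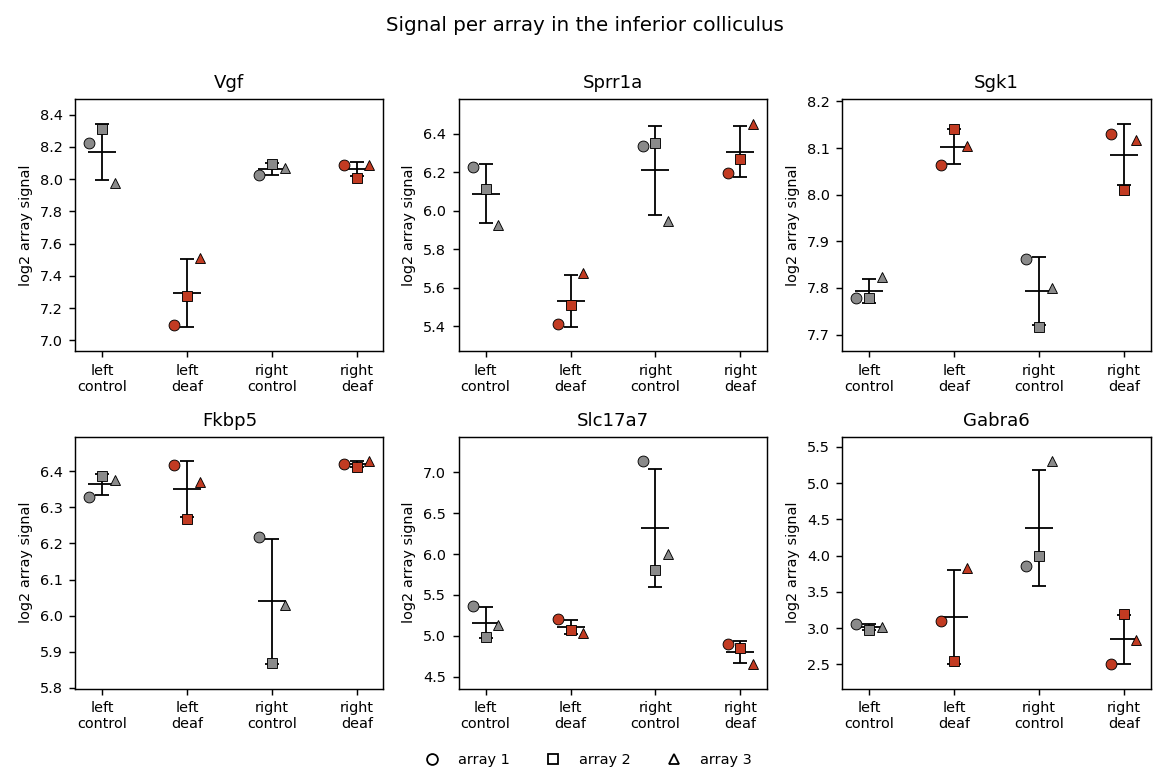
Log2 array signal of 6 named genes in the 4 groups; each point is an array, the bar is the mean and the error bar the SD (n = 3). The 3 left deaf arrays of Vgf have a mean of 7.29, against 8.17, 8.06 and 8.06 in left control, right control and right deaf arrays.

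In the right IC, on the side of the ablated ear, cerebellar markers were lower in deaf than in control arrays: 17 of 21 measured members had lower means (average change -0.31; camera adjusted p = 2.8e-05; adjusted p = 0.176 with an estimated correlation). Gabra6, a granule cell GABA receptor subunit gene (Entrez 29708), differed by -1.54 (SE 0.37), Cbln3 (Entrez 501998) by -1.19 (SE 0.28) and Fat2 by -0.88 (SE 0.26); these 3 fell when adjusted over the list alone (limma adjusted p = 0.0143, 0.0143 and 0.0428). The right deaf mean of Gabra6, 2.84, lay below the lower quartile of the array values, 3.78, where background limits the size of a difference. Slc17a7, the vesicular glutamate transporter 1 gene (Entrez 116638), is not a member of that list. Within the glutamate list it was lower by 1.51 (SE 0.26, limma adjusted p = 0.00279 over the list alone). Its right control mean, 6.31 (SD 0.72), lay above left control (5.16), left deaf (5.10) and right deaf (4.80). Gabra6 likewise was highest in right control, at 4.38, against 3.02, 3.15 and 2.84. Whether Slc17a7 and the cerebellar markers differ for the same reason was not tested. The cerebellar score was 0.17, 0.033 and 0.43 on right controls 1, 2 and 3, and -0.093 ± 0.020 (SD, n = 3) in right deaf arrays. Without right control 3 the average change was -0.20. Among genes above the median level the list had a camera adjusted p of 0.143. That filter removes dim members such as Gabra6, here and in the other contrasts, so it cannot show whether their differences are stable. With 1 array left out, Gabra6 and Cbln3 were lost in 2 of 12 fits (0.0770 without right deaf 1, 0.0563 without right deaf 3) and Fat2 in 8 (up to 0.201, without right control 3, where it was at -0.57), and Slc17a7 was lost in none (up to 0.0181).

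Glucocorticoid-responsive genes were higher in the right deaf IC, in 17 of 20 members and by 0.13 on average (camera adjusted p = 6.0e-05; adjusted p = 0.176 with an estimated correlation). Adjusted over the list alone 5 of the 20 rose: Fkbp5 (0.38, SE 0.091), Sgk1 (0.29, SE 0.074), Zbtb16 (0.34, SE 0.090), Lcn2 (0.44, SE 0.12) and Per1 (0.38, SE 0.12). The 4 first named had limma adjusted p = 0.0191, 0.0191, 0.0203 and 0.0222. Fkbp5 was lowest in right control, at 6.04 (SD 0.17), against 6.36 in left control, 6.35 in left deaf and 6.42 in right deaf. Sgk1 was at 7.79 in both control groups, 8.10 in left deaf and 8.09 in right deaf. Myelin and oligodendrocyte markers were lower in 19 of 20 members, with a mean of -0.11 (camera adjusted p = 6.0e-05; adjusted p = 0.179 with an estimated correlation), as in Ugt8 (-0.30, SE 0.10) and Cnp (-0.23, SE 0.087), which did not pass alone. With right deaf 1 left out, the 5 glucocorticoid members had adjusted p between 0.0907 and 0.0933 over the list alone; Per1 was lost in 5 of 12 such fits, Lcn2 in 4, Zbtb16 in 3 and Fkbp5 and Sgk1 in 2.

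Circadian clock genes were higher by 0.080 on average, in 13 of 17 members (camera adjusted p = 0.0372; adjusted p = 0.179 with an estimated correlation), including Per1 and Per2 (0.35, SE 0.12). Immediate early genes were higher by 0.098, in 18 of 27 members (camera adjusted p = 0.0372; adjusted p = 0.564 with an estimated correlation), with values of 0.20 (SE 0.10) for Egr1 and 0.40 (SE 0.21) for Npas4, neither of which passed. Choroid plexus and ependymal markers were higher by 0.13, in 13 of 20 members (camera adjusted p = 0.0316; adjusted p = 0.381 with an estimated correlation), with cilium genes Spag6l at 0.54 (SE 0.21) and Cfap126 at 0.46 (SE 0.19), neither passing. Without right deaf 1 Npas4 was at 0.14, and without right control 3 Per2 was at 0.23 and Cfap126 at 0.26. Without right control 1 Cfap126 was at 0.70. Leaving out 1 array ended each of these calls. Immediate early genes had an adjusted p of 0.616 without right deaf 1 (mean change 0.043), 0.108 without right control 2 and 0.117 without right control 3, and a mean change of 0.15 without right deaf 3. The clock list had 0.278 without right deaf 3, 0.211 without right control 1 and 0.0855 without right control 2. The choroid and ependymal list had 0.179 without right control 3 (mean change 0.074), 0.106 without right deaf 2 and 0.0649 without right deaf 3. Among genes above the median level the immediate early and choroid lists were not called (0.0593 each).

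Other right-side genes are given as values that did not pass. Higher values were found for Prdm9 (0.50, SE 0.094), Tulp2 (0.31, SE 0.079), Gast (0.48, SE 0.12), Srpk3 (0.32, SE 0.082) and Actrt3 (0.49, SE 0.13). Lower values were found for Cd209al3 (-0.52, SE 0.11), Sirpal1 (-0.63, SE 0.16) and Lipi (-0.44, SE 0.11). The haemoglobin gene Hbb-b1 was at -0.48 (SE 0.16), the glycine receptor gene Glra1 at -0.40 (SE 0.16) and the neurofilament gene Nefh at -0.29 (SE 0.11). Without right control 1 Glra1 was at -0.23 and Nefh at -0.18, and without right deaf 3 Hbb-b1 was at -0.31. With limma 0 of 18166 genes passed (smallest adjusted p = 1.00), against 783 at an unadjusted p under 0.05 (385 higher, 398 lower). Arrays did not overlap for 1358 genes (7.48%), where chance gives 10%. Of the 28 lists 6 were called (5 to 9 with 1 array left out, and 9 without right deaf 2), and none with an estimated correlation or with the directional test of fry. The meningeal list turned direction: camera called it lower without right deaf 2 (0.0319), but higher without right deaf 3 (0.00433) or right control 1 (0.0479). The oligodendrocyte precursor, forebrain, endothelial, microglia and blood lists were called lower in some of these fits. The mixed test of fry called the glucocorticoid list (adjusted p = 0.00116; 0.0570 without right deaf 1) and the glutamate list (0.0470), which was lost in 10 of 12 fits with 1 array left out (up to 0.907, without right deaf 1).

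**Figure D2:**
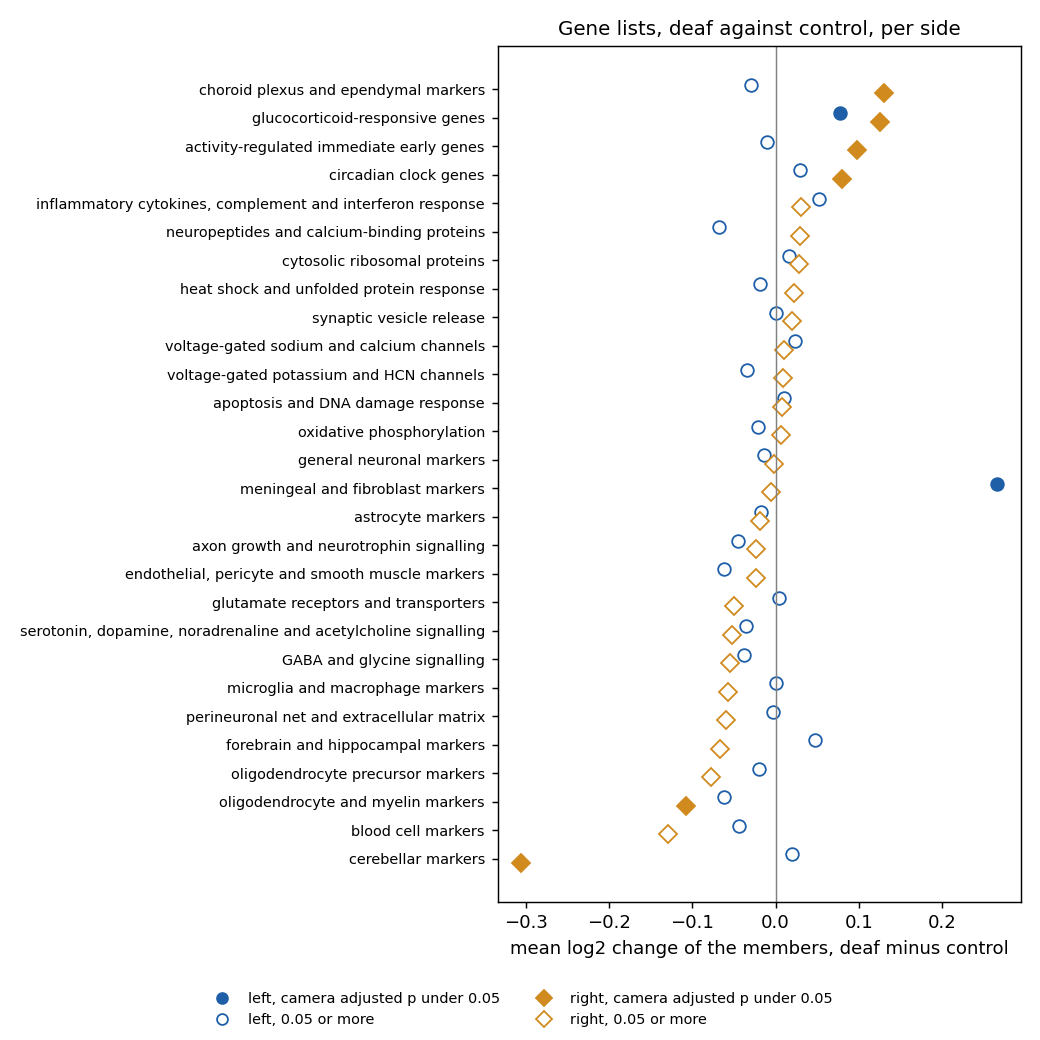
Mean log2 change of the measured members of 28 gene lists, deaf minus control, for the left (circles) and right (diamonds) IC; filled symbols are lists with a camera adjusted p under 0.05. The cerebellar list lies at -0.31 on the right and 0.019 on the left.

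Averaged over both sides, glucocorticoid-responsive genes were higher and myelin markers lower in deaf arrays by camera at the preset correlation. Neither list was called with an estimated correlation (adjusted p = 0.198 and 0.287) or by the directional test of fry. The mean myelin score was highest in right control, at 0.082, against 0.0030 in left control, -0.058 in left deaf and -0.026 in right deaf. Whether this shares a source with the cerebellar pattern was not tested. Sgk1 (Entrez 29517) was at 8.01 to 8.14 on the 6 deaf arrays and at 7.72 to 7.86 on the 6 control arrays, a rise of 0.30 (SE 0.052; limma adjusted p = 0.00189 over the list alone), and Zbtb16 rose by 0.27 (SE 0.064; limma adjusted p = 0.0138). The glucocorticoid list was higher in 16 of 20 members, by 0.10 on average (camera adjusted p = 1.2e-05; adjusted p = 0.198 with an estimated correlation). The myelin list was lower in 17 of 20 members, with a mean of -0.085 that came from -0.11 on the right and -0.061 on the left, where it was not called (0.135) (camera adjusted p = 4.0e-05; adjusted p = 0.287 with an estimated correlation), and its members Ugt8 (-0.28, SE 0.073) and Cnp (-0.23, SE 0.061) fell, each with a limma adjusted p of 0.0302 over the list alone. The cerebellar list was lower in 15 of 21 members, with a mean of -0.14 (camera adjusted p = 0.0154; adjusted p = 0.446 with an estimated correlation), and its adjusted p was 0.158 without right control 3 (mean -0.088), 0.0682 without left control 2 and 0.330 among genes above the median level. With 1 array left out 2 to 4 lists were called. The meningeal list (without left control 1, right control 1, left deaf 1, left deaf 3 or right deaf 3; adjusted p up to 0.0215), the endothelial list (without right control 2, right control 3, left deaf 2 or right deaf 2; up to 0.0363) and the clock list (without left control 3 or right deaf 1; up to 0.0412) were then called as well. These p-values take left and right arrays as separate animals, which the labels do not state.

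Over their lists alone, Sv2c, a synaptic vesicle gene (-0.39, SE 0.094, limma adjusted p = 0.0348), Slc17a7 (-0.78, SE 0.19, adjusted p = 0.0347) and Vgf (-0.44, SE 0.080, adjusted p = 0.00448) also fell. The 2 last means come from unequal sides: Slc17a7 was at -0.058 on the left and -1.51 on the right, and Vgf at -0.88 on the left, with means of 8.06 in both right groups. Krtap10l1 (0.33, SE 0.082), Bco1 (0.34, SE 0.12), Tat (-0.36, SE 0.087) and Wnt9b (-0.31, SE 0.086) did not pass, and Bco1 was at 0.22 without right control 1. With each array left out in turn, Sgk1, Zbtb16 and Vgf stayed past the threshold over their lists in all 12 fits, whereas Ugt8, Cnp and Slc17a7 were lost in 9 (up to 0.0936, 0.0936 and 0.108) and Sv2c in 10 (up to 0.106). Over all genes limma called 0 of 18166 (smallest adjusted p = 0.859), against 823 at an unadjusted p under 0.05. All 6 deaf arrays lay beyond all 6 control arrays for 49 genes (0.270%), where chance gives 0.216%. Exact permutation of the list scores, with arms exchanged within sides, gave p = 0.01 for the glucocorticoid, myelin and circadian clock lists (0.0933 each, adjusted over 28 lists). The clock list was higher by 0.054 on average, in 13 of 17 members, and was not called by camera (adjusted p = 0.0686). The mixed test of fry called the glucocorticoid list (adjusted p = 1.9e-04; up to 0.00406 with 1 array left out) and the myelin list (0.0394), which was lost in 9 of 12 such fits (up to 0.281, without right deaf 1).

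**Figure D3:**
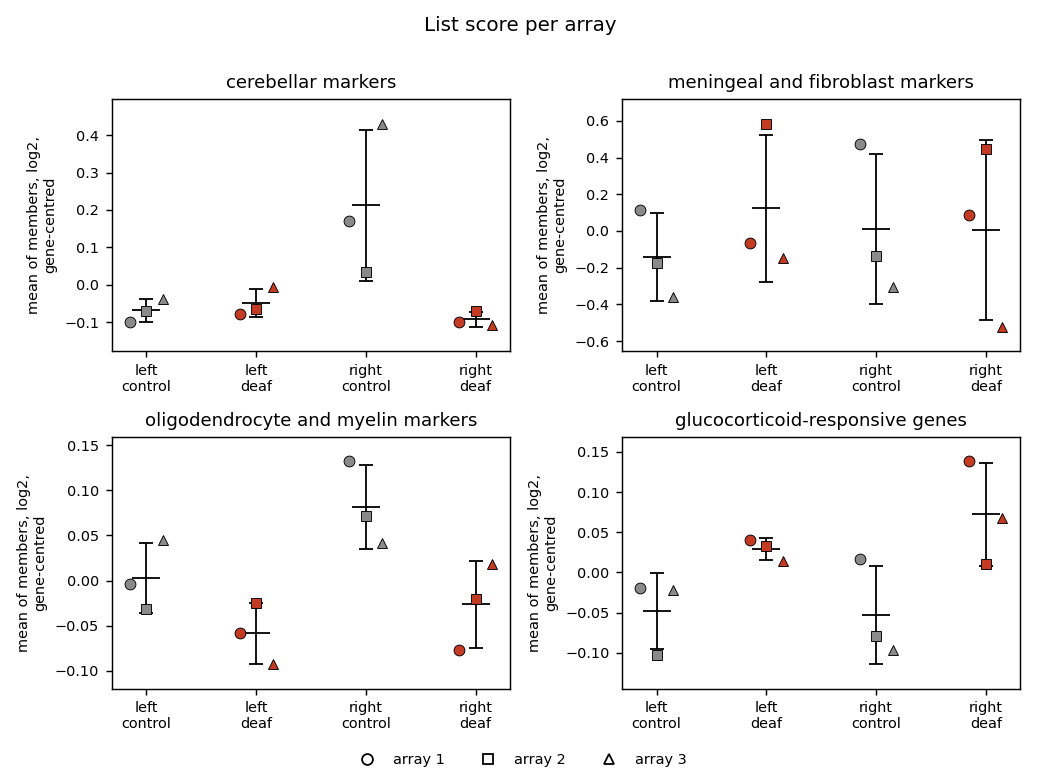
Score per array (mean gene-centred log2 value of the members) of 4 lists in the 4 groups; bars are means and error bars the SD (n = 3). Right control 3 has the highest cerebellar score, at 0.43, and left deaf 2 the highest meningeal score, at 0.58.

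Between the sides of control rats, the left IC had lower cerebellar, forebrain and myelin marker values than the right IC. The cerebellar list averaged -0.28 left minus right (17 of 21 lower; camera adjusted p = 4.1e-04; adjusted p = 0.418 with an estimated correlation), with Gabra6 at -1.37 (SE 0.37), Cbln3 at -0.94 (SE 0.28) and Neurod1 at -0.53 (SE 0.18), which did not pass and were at -0.91, -0.55 and -0.29 without right control 3. Gabra6, at 3.02 in left control arrays, was below their lower quartile of 3.78. The forebrain list averaged -0.14 (13 of 20 lower; camera adjusted p = 0.0462) with Neurod2 at -0.61 (SE 0.16), and the myelin list -0.079 (16 of 20 lower; camera adjusted p = 0.0320). Both had an adjusted p = 0.418 with an estimated correlation, and neither was called after quantile normalization (0.0750 and 0.0794). Among genes above the median level the cerebellar list had 0.501 and the forebrain list 0.986. Without right control 3 the cerebellar list averaged -0.17. Slc17a7 (-1.15, SE 0.26, limma adjusted p = 0.0261), Fkbp5 (0.32, SE 0.091) and Arrdc2 (-0.32, SE 0.092), both at 0.0466, differed over their lists alone.

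In this comparison, leaving out 1 array gave adjusted p values up to 0.328 for myelin (right control 1) and 0.124 for forebrain (right control 3). The number of lists called was 3 with all arrays, 1 without left control 2 or right control 2, and 7 without right control 3. The 5 gained without right control 3 were the blood, GABA and glycine, neuronal, meningeal and microglia lists, lower on the left (adjusted p from 0.00558 to 0.0480). Fkbp5 and Arrdc2 were each lost over the list alone in 11 of 12 such fits (up to 0.216 and 0.226), and Slc17a7 in 2 (0.141 without left control 2, 0.101 without left control 3; its change was -0.74 without right control 1). The myelin call was also lost without left control 1 (0.0682), left control 2 (0.0942) and right control 2 (0.0504). The forebrain call was also lost without left control 2 (0.0888), left control 3 (0.110), right control 2 (0.0914) and left deaf 1 (0.0502). Hdac6 (0.37, SE 0.080), Cdhr4 (0.73, SE 0.16), Tmem132d (0.45, SE 0.10), Pramel36l1 (-0.70, SE 0.13), Trim6 (-0.62, SE 0.12) and Zfp14 (-0.45, SE 0.091) did not pass. With limma 0 genes passed (smallest adjusted p = 0.477), against 900 at an unadjusted p under 0.05. Arrays did not overlap for 1780 genes (9.80%), where chance gives 10%.

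Between the sides of deaf rats, immediate early genes had lower values on the left, in 24 of 27 members and with a mean of -0.12 (camera adjusted p = 7.0e-04; adjusted p = 0.638 with an estimated correlation). Egr1 (-0.40, SE 0.10), Egr3 (-0.25, SE 0.093) and Dusp5 (-0.21, SE 0.091) did not pass over the list alone, and Egr3 was at -0.17 without right deaf 3. The list had an adjusted p of 0.351 without right deaf 1 (mean -0.067), 0.0708 without left deaf 2 and 0.0916 without left deaf 3. The number of lists called was 1 with all arrays, 0 without left deaf 2 or right deaf 1, and 2 without left deaf 3 (meningeal higher and neuropeptides lower, 0.0178 each) or right deaf 2 (meningeal, 6.1e-04). Vgf (-0.77, SE 0.11) and Sprr1a (-0.77, SE 0.13) were lower on the left over the list alone (limma adjusted p = 6.4e-04 and 9.9e-04), but not over all genes (0.133 and 0.309). Both stayed past the threshold over the list alone in all 12 fits with 1 array left out (up to 0.00432 and 0.00737). The mixed test of fry called their list (adjusted p = 0.00187), but not without left deaf 2 (0.0968), right deaf 1 (0.0587) or right deaf 3 (0.117). Serpinb6b (0.69, SE 0.14), Prss57 (0.38, SE 0.093), Car13l1 (0.53, SE 0.14) and Cenpu (-0.49, SE 0.11) did not pass. With limma 0 genes passed, against 607 at an unadjusted p under 0.05. Arrays did not overlap for 1510 genes (8.31%), where chance gives 10%.

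The interaction asked whether the change with deafness differed between the sides. The cerebellar list differed by 0.32 on average (17 of 21 members higher; camera adjusted p = 6.0e-04; adjusted p = 0.553 with an estimated correlation). It was the 1 list called with all arrays. Camera called 3 lists without left control 2, right control 2, left deaf 1, left deaf 3 or right deaf 3, and 2 without left control 1, right control 3, left deaf 2, right deaf 1 or right deaf 2. The lists gained were meningeal, choroid, immediate early, neuropeptide and forebrain (adjusted p from 6.3e-05 to 0.0488), and none of them was gained in all of these fits. Vgf differed by -0.88 (SE 0.16; limma adjusted p = 0.00457 over the list alone, 0.711 over all genes). Over the list alone its adjusted p was up to 0.0177 with 1 array left out. The cerebellar list had 0.645 among genes above the median level, and differed by 0.21 without right control 3. Tnp1 (0.55, SE 0.11), Spint3 (0.97, SE 0.23), Slc17a7 (1.45, SE 0.37), Actbl2 (-0.79, SE 0.15) and Prl3d4 (-0.85, SE 0.17) did not pass. Glucocorticoid-responsive genes (camera adjusted p = 0.449) and myelin markers (0.368) were not shown to differ between the sides. Of 18166 genes limma called 0 (smallest adjusted p = 0.0926), against 622 at an unadjusted p under 0.05. Across genes, which are not independent replicates, left and right changes had a Pearson r of 0.033 and a Spearman rho of 0.047. In none of the 6 contrasts was a list called with an estimated correlation or with the directional test of fry, and its mixed test called none in the interaction or between the sides of control rats.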

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

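The tests of the explanations in this part were chosen after the results were seen.

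The cerebellar list differed between the sides in its change with deafness (camera adjusted p = 6.0e-04, and 0.0286 without right control 3). It was not called with an estimated correlation (0.553). Among genes above the median level, which leave out dim members such as Gabra6, it was not called either (0.645). Right control arrays exceeded left control arrays by 0.28 in the mean score, whereas right deaf arrays lay within the spread of left controls (difference -0.024, pooled SD 0.026). This is what cerebellar tissue in the right control samples would give. The mean score of forebrain markers was also higher in right than in left controls (0.077 against -0.067). Whether such tissue would raise these as well was not tested. The abundant cerebellar list members Pcp4 (10.57 in right control, 10.66 in right deaf) and Pvalb (9.14 and 9.16) did not differ in that direction, but a high IC level could hide a small admixture. Other lists also hold Grm4, Calb1 and Pvalb. Right control 3 as the only source on the right is argued against, since camera at the preset correlation called the list without it (adjusted p = 0.00905). That was the highest of 12 fits with 1 array left out, the lowest being 1.5e-07. The average change was smaller without that array. With an estimated correlation camera did not call the list on the right even with all arrays (adjusted p = 0.176). Right-sided expression in sham rats that deafness lowers cannot be told apart from such tissue: the SD of right controls was 5.29 times the largest other SD, which passed the bound but not beyond the spread that 3 arrays allow.

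Vgf differed between the sides in its change with deafness (limma adjusted p = 0.00457 over the list alone; up to 0.0177 with 1 array left out). Fewer neurons in general are argued against, because the median change of 19 neuronal markers in the left IC was 0.0095. Its SE of 0.033 was taken over the markers, which are not replicates. Over the arrays, the neuronal score was -0.0088 (SD 0.049) in left control and -0.023 (SD 0.034) in left deaf. The change of Vgf was -0.88. A change limited to some types of neuron was not tested. Chance among all genes tested stays open: over all genes the limma adjusted p was 0.711 for the interaction and 0.110 for the left change. All 9 arrays of the other groups lay above the 3 left deaf arrays, which lower Vgf with deafness opposite the ablated ear would give, and that biological explanation may hold but was found and tested on the same arrays.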

How the results depend on the processing

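The tests without right controls 1 and 3 together, with the meningeal score as a covariate, by exact permutation, and of members over the list alone, by the mixed test of fry and of list means with arrays left out were chosen after the data were seen, the others before the data were examined. For each change below the cause was not tested unless stated. No gene count moved under quantile normalization, centring, all probes, mean of probes, array weights, the compared groups alone or a random block of arm and number. Vgf on the left had adjusted p from 0.00221 to 0.914 over all alternatives. Among 4467 alternative values of 205 named gene results, 4457 kept their direction and side of the threshold. None had passed over all genes in the main fits, and they were picked for small p on the same arrays. This count therefore says little about their stability.

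Genes above the median level gave 1 gene on the left (Vgf, 0.0113) and 1 between sides in deaf rats (0.0481), where fewer genes were tested. A variance trend with robust estimation gave 1 (Vgf, 0.00221) and 2 (Vgf and Or52a5b, 0.0129). A replicate block gave 1 gene between sides in control rats and 1 in the interaction, RGD1565183 both times. Unadjusted p under 0.05 with 1.5-fold gave 31, 39, 5, 69, 29 and 156 genes in the order left, right, both (Slc17a7, Mirlet7f-1os, Or1o11b, Slc5a7 and Gabra6), sides in control, sides in deaf and interaction. Adjusted p under 0.1 gave 1 in the interaction (Mirlet7f2). Leaving out each array gave 0 to 1 genes on the left (Vgf, 0.0482 without left deaf 3) and 0 to 1 for both sides (Clec2d2, 0.0362 without right control 3), and 0 elsewhere. Or52a5b, RGD1565183, Mirlet7f2, Mirlet7f-1os, Or1o11b, Slc5a7 and Clec2d2 were named after their values were seen.

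Lists by camera adjusted p: quantile normalization gave 0.0750 for forebrain and 0.0794 for myelin between control sides. Genes above the median level gave 0.0593 for immediate early, 0.143 for cerebellar and 0.0593 for choroid on the right, 0.330 for cerebellar on both sides, 0.501 for cerebellar and 0.986 for forebrain between control sides, and 0.645 for the cerebellar interaction. The cerebellar values leave out dim members such as Gabra6 and say nothing about them. With an estimated correlation, values were 0.775 for glucocorticoid and meningeal on the left; 0.564 immediate early, 0.176 cerebellar, 0.381 choroid, 0.179 clock, 0.176 glucocorticoid and 0.179 myelin on the right; 0.446 cerebellar, 0.198 glucocorticoid and 0.287 myelin on both sides; 0.418 for the 3 lists between control sides, 0.638 immediate early between deaf sides and 0.553 cerebellar in the interaction. With the directional test of fry they were 0.731 glucocorticoid and 0.852 meningeal on the left, 0.681 immediate early, 0.0914 cerebellar, clock, glucocorticoid and myelin and 0.532 choroid on the right, 0.507 cerebellar, 0.0971 glucocorticoid and 0.120 myelin on both sides, 0.327 for the 3 lists between control sides, 0.530 between deaf sides and 0.580 in the interaction.

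Without right controls 1 and 3 the right lists had 0.114 (immediate early), 0.296 (cerebellar), 0.435 (choroid) and 0.258 (clock). Right control 2 is then alone in its group and is assumed to vary like the other groups, and the arrays with the highest cerebellar scores are gone, so these values say nothing about stability. The meningeal covariate gave 0.0883 for glucocorticoid and 0.839 for meningeal on the left. The meningeal value follows from fitting that list's own score as the covariate, so it says nothing about the list. Among genes above the median level 6 lists were called on both sides, 5 between control sides and 2 between deaf sides, and with the meningeal covariate 1 on the left and 6 on both sides. With that covariate the 1 on the left was the endothelial list, lower (camera adjusted p = 1.9e-04), which was also gained on both sides (0.00109). Exact permutation on both sides gave 0.525 for cerebellar and 0.0933 for glucocorticoid and myelin. Leaving out each array gave ranges of 0.0283 to 0.345 (glucocorticoid, left), 4.4e-05 to 0.715 (meningeal, left), 0.00126 to 0.616 (immediate early, right), 0.00796 to 0.179 (choroid, right), 0.0231 to 0.278 (clock, right), 2.9e-04 to 0.158 (cerebellar, both), 0.0209 to 0.124 (forebrain, control sides), 0.00386 to 0.328 (myelin, control sides) and 1.7e-07 to 0.351 (immediate early, deaf sides).

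Rpl10 on the right changed sign with the mean of probes (0.035) and without right controls 1 and 3 (0.0015), where Bcl2l11 (0.019) and Mgp (0.14) did too; Kcnq5 ran from -0.0071 to 0.27 when 1 array was left out. Same-numbered left and right arrays had correlations of 0.10, -0.013 and 0.057 in control and 0.15, -0.056 and -0.043 in deaf rats, with the own number the best match in 3 of 6, so the numbers were not taken to pair the samples, and whether they share rats stays open. Signal over background limits dim genes such as Gabra6, at 2.84 in right deaf arrays.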

Other observations

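The tests of the glucocorticoid pattern and with the meningeal covariate were chosen, and the lists called under only some settings named, after the results were seen, and the splits of the arrays before the data were examined.

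Several lists of cell types and transmitter systems were not called for deafness on either side with all genes and arrays. Microglia and macrophage markers averaged 1.1e-04 on the left and -0.057 on the right (camera adjusted p = 0.966 and 0.308), and inflammatory genes 0.052 and 0.031 (0.516 and 0.603). Astrocyte markers averaged -0.018 and -0.019 (0.539 and 0.424), GABA and glycine genes -0.038 and -0.055 (0.629 and 0.458), and perineuronal net genes -0.0032 and -0.060 (0.979 and 0.310). Blood cell markers averaged -0.044 and -0.13 (0.630 and 0.0570). On the right, microglia markers were called lower without right control 3 (0.0300) or right deaf 2 (0.0319), and blood markers without left deaf 1 (0.0388), left deaf 2 (0.0433) or right deaf 2 (0.0165) and with the meningeal covariate (0.0215). Among genes above the median level, blood markers were called lower on the left (0.0258) and right (0.00108) and astrocyte markers on the right (0.0479).

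Glucocorticoid-responsive genes were higher in deaf arrays of both sides, in 16 of 20 members. Averaged over both sides, the list was not called by camera with an estimated correlation (adjusted p = 0.198) or by the directional test of fry (0.0971). Meningeal tissue in some samples is argued against as the whole explanation, since the mean change was 0.098 (SE 0.031) with the meningeal score as a covariate and 0.10 (SE 0.029) without it, although the call on the left alone ended (0.0883), and so is Sgk1 alone (adjusted p = 1.8e-04 without it). The exact permutation p of the list score was 0.01, but 0.0933 adjusted over 28 lists, so chance among correlated list members cannot be told apart from a higher list score, although the mixed test of fry, which takes either direction, gave 1.9e-04. Sampling at another time of day cannot be told apart either: the clock list had the same permutation p (13 of 17 members higher), Per1, Per2 and Per3 averaged 0.20, and genes in antiphase -0.016, from -0.071 (SE 0.082) for Bmal1, the direction of a shift, to 0.010 for Cry1. A response to deafness or to the surgery may remain among the explanations, but sham rats had no drilling, so these are not separated, and 4 of the list's members also stand in other lists.

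Other splits of the same arrays were fitted in the same way and their genes at unadjusted p under 0.05 counted. Each number of splits below, and its total, includes the real grouping. For the left, 5 of 10 splits gave at least 670 genes (highest other 910), for the right 8 of 10 gave at least 783 (1947), between sides in control rats 5 of 10 gave at least 900 (1473), and between sides in deaf rats 9 of 10 gave at least 607 (1097); these splits are too few for a share under 0.05. For both sides 48 of 100 splits gave at least 823 genes and for the interaction 89 of 100 gave at least 622, with 2125 as the highest other in each, so chance was not excluded. A split with several times the real count, as in 1947 against 783 on the right and 2125 against 823 for both sides, may reflect a structure of the samples that the groups do not describe, but what correlated genes give by chance was not tested.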
